A study of Arabidopsis thaliana with 12 samples.

How the data were processed

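The study sequenced mRNA from whole seedlings of Arabidopsis thaliana, of the Col-0 accession and of dcp5-1, a mutant of the decapping factor gene DCP5 in that background. Per the labels, seeds were kept at 4 °C for 3 days, seedlings grew on 1x MS agar for 5 days at 22 °C with 16 h light and 8 h dark, rested for 30 min in 1x MS liquid medium, and then spent 0 or 60 min in liquid medium with 150 mM NaCl. There are 3 libraries for each of the 4 groups, 12 in all. The labels do not say whether replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

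The deposited table, which the authors made, holds FPKM (fragments scaled to transcript length and library size) for 38088 loci in 12 columns, and all 12 were used. A last line without values was dropped. The submitters' processing notes name Bowtie, without a version, and the TAIR10 genome build. The quantification program and the annotation are not given in the sources used here. Locus identifiers of 37792 loci matched a TAIR10.1 annotation table, which gave symbols, biotypes, transcript lengths and GC contents; by that annotation DCP5 (AT1G26110) lies on chromosome 1 from 9024341 to 9027955.

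The values are not counts, but whole read numbers could be recovered for part of them. Over 14027 nuclear genes with a single transcript of more than 1000 nt, 98.4% to 99.0% of the values below 10 reads were within 0.1 read of a whole number after a length correction and 1 scale factor per library were fitted. The scale factors stand for 14520000 to 20980000 reads, and the recovered reads in these genes sum to 6040000 to 6780000 per library, with a median of 43 to 63 reads per gene. For pairs of replicates the squared difference over its counting variance averaged 1.908 to 10.366 per gene; the highest value belonged to replicates 1 and 2 of Col-0 at 0 min, so the spread there was well above counting error. Loci above 0 numbered 23810 to 24223 per library. Log2 values of nuclear protein-coding genes correlated at r = 0.986 to 0.992 across genes within groups and at 0.881 to 0.975 between groups, and the first 3 principal components held 67.5%, 17.4% and 3.87% of the variance.

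Values were analysed as log2(FPKM + 1), with a pseudocount of 1, for the 19876 loci with a mean of at least 1 FPKM over the 12 libraries, 18708 of them nuclear and protein-coding. Fold changes on this scale understate those of genes with low values. A linear model with the 4 group means was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes variances that follow a trend on mean expression (8 residual and 3.29 prior degrees of freedom). The contrasts were salt against 0 min in Col-0, the same in dcp5-1, dcp5-1 against Col-0 at 0 min and at 60 min, their interaction, and the mean salt response. Tests are two-sided, with Benjamini-Hochberg adjustment over all genes tested in a contrast, and genes are called at an adjusted p below 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.

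Before the data were examined, 30 gene lists with 452 members were fixed from general knowledge of Arabidopsis genes: ABA effectors, ABA synthesis and breakdown, clade A PP2C phosphatases, ABA receptors, stress transcription factors, ion transport, proline with raffinose and starch, decapping and P-body components, deadenylation and tandem zinc finger proteins, stress granule and translation initiation proteins, jasmonate, ethylene, auxin, cell wall growth, aquaporins, photosynthesis, cytosolic ribosomal proteins, ribosome biogenesis, heat shock, redox, salicylic acid, flavonoids and glucosinolates, nutrition, seed storage, hypoxia, clock, root, stomatal, vascular and cell division genes. The reference table gives the same symbol or synonym for 434 members, another spelling or none for 18, and contradicts 0; 420 were tested. Each list was tested against the other genes with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists of a contrast. Of 150 tests over 5 contrasts 42 passed, and 4 hold with an estimated correlation. Median and mean differ in sign for 15 of the 150, none of which passed.

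Genes named are DCP5, the 5 genes with the largest rise and the 5 with the largest fall per contrast among those with a symbol, called, at a mean of at least 5 FPKM in the higher group and without overlap between the libraries, and up to 2 called members per direction in lists that passed or had most calls. This rule, the tests and the main alternatives were set before the data were examined; the minimum of 5 was planned in CPM and applied to FPKM. RBCS1A and MIR852, listed at 0 in whole groups, are given no fold. The result of 1 gene that the rule selects is not reported. The size of the response in dcp5-1 was tested by regrouping the genotypes within each time, which is exact only if genotype has no effect at either time.

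The pipeline was tested on simulated data: of 67, 67 and 66 genes with a mean log2 value above that of 5 FPKM, given a log2 change of 0.5, 1 and 2 among 19876, 82.1%, 98.5% and 100% were recovered, and 7 of 19676 unchanged genes were called. In a simulated comparison without any change 0 of 19876 were called. The simulated noise was independent between genes, with 1 spread per gene for all groups and no trend with transcript length or abundance. These rates therefore leave out errors from such trends or from a wider spread in 1 group.

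Alternatives were another pseudocount, no filter, a threshold of 1 log2 unit, fits on the 6 libraries compared, a block for replicate number, leaving out organelle genes and leaving out each library in turn. Chosen after the data were examined were nuclear protein-coding genes only, median-of-ratios rescaling, quantile normalization, no variance trend, a mean of at least 5 FPKM, leaving out genes with an exact 0, and removal of each library's trend with transcript length alone or with length, GC content and abundance, by splines with 5 degrees of freedom, which also re-centre each library. The count-based tests, size factors and count filters planned at first were not run, because the values are not counts.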

Results

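The transcript that carries the dcp5-1 mutation was lower in the mutant in every library. DCP5 encodes an LSM14-family partner of the mRNA decapping complex. At 0 min it had 50.7 ± 1.99 FPKM in Col-0 and 13.0 ± 0.105 FPKM in dcp5-1 (mean ± SD, n = 3). The mutant level was 25.7% of the Col-0 level (log2 fold change -1.88, SE 0.047, limma with Benjamini-Hochberg adjusted p = 6.38e-10). After 60 min in 150 mM NaCl DCP5 had 80.1 ± 4.26 FPKM in Col-0 and 20.5 ± 0.22 FPKM in dcp5-1 (log2 fold change -1.92, limma adjusted p = 5.25e-10). DCP5 rose between 0 and 60 min by 0.65 log2 units in Col-0 (limma adjusted p = 1.65e-07) and by 0.62 in dcp5-1 (limma adjusted p = 3.45e-07). These rises did not differ detectably (interaction -0.03, SE 0.066, limma adjusted p = 0.751), except with quantile normalization (interaction -0.44, limma adjusted p = 0.00045). The libraries came from 5-d-old seedlings, with 3 libraries for each genotype and time.

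**Figure D1:**
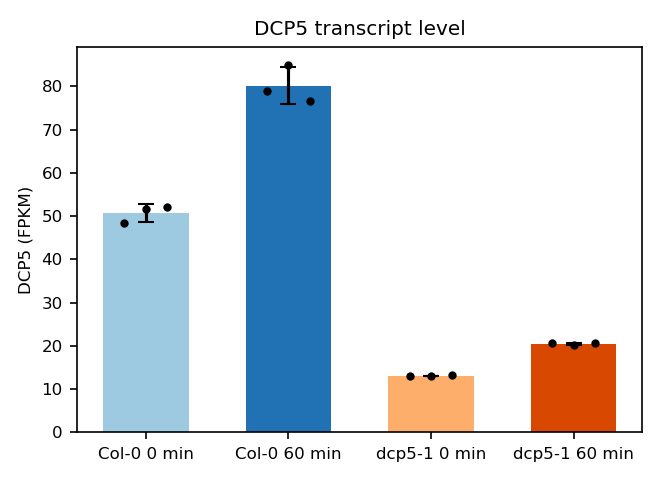
DCP5 in FPKM (linear axis from 0) in Col-0 and dcp5-1 at 0 and 60 min; bars are means of 3 libraries, error bars are SD and points are libraries. Both dcp5-1 groups, at means of 13.0 and 20.5 FPKM, lie below both Col-0 groups, at 50.7 and 80.1 FPKM.

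In Col-0, RD29A, a marker of the dehydration response, rose from 12.0 ± 1.77 FPKM at 0 min to 373 ± 9.75 FPKM at 60 min (mean ± SD, n = 3; log2 fold change 4.86, SE 0.083, limma with Benjamini-Hochberg adjusted p = 1.68e-12). RD26, a NAC transcription factor of abscisic acid (ABA) signalling, rose from 16.1 ± 2.55 to 346 ± 14.1 FPKM (log2 fold change 4.35, SE 0.117, limma adjusted p = 5.64e-11). PUB19, a ubiquitin ligase gene of drought signalling, rose from 4.43 ± 0.611 to 134 ± 0.251 FPKM (log2 fold change 4.64, SE 0.076, limma adjusted p = 1.27e-12). HSFA6B, a heat shock factor acting in ABA responses, rose from 0.0973 ± 0.0494 to 28.2 ± 1.26 FPKM. Of the steepest falls, that of PHI-1 was from 531 ± 107 to 6.41 ± 0.363 FPKM. Next came the brassinosteroid-responsive gene EXO (763 ± 40.9 to 10.7 ± 0.481 FPKM), and the jasmonate repressor gene JAZ8 (140 ± 9.5 to 1.78 ± 0.513 FPKM). The touch-induced xyloglucan enzyme gene TCH4 (852 ± 41.7 to 15.8 ± 0.698 FPKM) and the transcription factor gene DREB26 (187 ± 11.4 to 3.22 ± 0.122 FPKM) fell too. Their log2 fold changes ran from -6.15 for PHI-1 to -5.48 for DREB26, with limma adjusted p of 8.98e-11 for JAZ8 and smaller values for the other 4. Of 19876 genes tested, 7223 were higher and 7092 lower at 60 min at an adjusted p threshold of 0.05. Of these, 1043 and 2132 changed by at least 1 log2 unit. No 60 min sample without NaCl is labelled, so these differences hold both the salt and 60 min more in liquid medium.

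**Figure D2:**
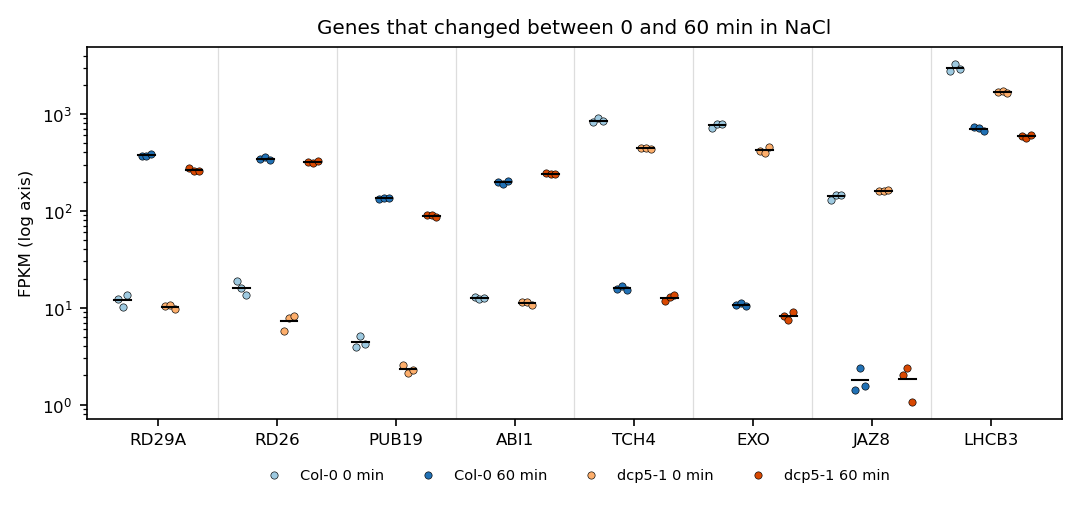
FPKM (log axis) of 8 genes in Col-0 and dcp5-1 at 0 and 60 min; points are libraries and short lines are means of 3 libraries. RD29A, RD26, PUB19 and ABI1 lie higher at 60 min than at 0 min in every library of both genotypes, and TCH4, EXO, JAZ8 and LHCB3 lie lower.

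Groups of genes fixed beforehand were compared next in Col-0. Of 18 ABA and dehydration effectors 16 were higher, 1 lower and 1 not called. Adjusted over the list alone the counts were 16 and 1 (median log2 fold change 1.77, camera adjusted p = 3.72e-07, adjusted p = 0.036 with an estimated correlation). The 1 lower member, the dehydrin gene RAB18, fell from 181 ± 6.18 to 123 ± 6.43 FPKM. Its direction was the opposite after trends with transcript length, GC content and abundance were removed (log2 fold change 0.22). The RAB18 call was also lost with quantile normalization (limma adjusted p = 0.433) and with the length trend alone removed (limma adjusted p = 0.71). All 8 measured clade A PP2C phosphatases, which restrain ABA signalling, were higher, also adjusted over the list alone (median 2.58, camera adjusted p = 5.71e-06, adjusted p = 0.0938 with an estimated correlation). Among them ABI1 rose from 12.6 ± 0.354 to 197 ± 5.76 FPKM and HAI2 from 0.261 ± 0.19 to 15.4 ± 0.473 FPKM. The 9 ABA receptors went the other way without passing, with 2 higher and 7 lower, the same adjusted over the list alone (median -1.77, camera adjusted p = 0.0662). Of 34 stress transcription factors 20 were higher, 13 lower and 1 not called, the same adjusted over the list alone (median 1.52, camera adjusted p = 0.0515). HB-12, a homeodomain factor induced by ABA, rose by 3.96 log2 units. DDF1, a factor of the DREB family, and WRKY18 fell by 4.92 and fell by 2.63 log2 units. Of 20 decapping and P-body components 17 were higher, 1 lower and 2 not called, the same adjusted over the list alone (median 0.69, camera adjusted p = 0.000144, adjusted p = 0.0983 with an estimated correlation). PAT1H2, a decapping activator, rose from 8.45 ± 1.08 to 23.8 ± 1.28 FPKM, and VCS, the scaffold of the decapping complex, from 6.14 ± 0.549 to 15.7 ± 0.462 FPKM. The 1 lower decapping member, LSM1A, had a log2 fold change of -0.65, which turned to 0.05 with the length trend alone removed and to 0.01 with all 3 trends removed.

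Growth and photosynthesis groups lay on the other side in Col-0. Of 14 cell wall growth genes 2 were higher, 11 lower and 1 not called, the same adjusted over the list alone (median -0.96, camera adjusted p = 0.00119, adjusted p = 0.197 with an estimated correlation). The xyloglucan enzyme gene XTH18 fell by 4.08 log2 units and the cellulose synthase gene CESA1 rose from 47.7 ± 0.374 to 87.4 ± 0.251 FPKM. Of 21 nuclear photosynthesis genes 2 were higher, 15 lower and 4 not called, the same adjusted over the list alone (median -0.83, camera adjusted p = 0.00144, adjusted p = 0.561 with an estimated correlation). LHCB3, a light-harvesting protein gene, fell from 2990 ± 268 to 707 ± 36.7 FPKM. GUN5, which encodes a subunit of Mg-chelatase, rose from 137 ± 11.7 to 376 ± 2.5 FPKM. Of 15 cytosolic ribosomal protein genes none was higher, 13 were lower and 2 not called, the same adjusted over the list alone (median -0.48, camera adjusted p = 0.00119, adjusted p = 0.561 with an estimated correlation). RPS13A fell from 613 ± 103 to 235 ± 7.18 FPKM. The 19 aquaporins had 2 higher, 14 lower and 3 not called, the same adjusted over the list alone (median -0.56, camera adjusted p = 0.0124, adjusted p = 0.664 with an estimated correlation). The water channel gene PIP2;7 fell from 1800 ± 265 to 685 ± 39.9 FPKM. Auxin responsive genes had 3 of 16 higher, 11 lower and 2 not called (median -0.65, camera adjusted p = 0.0498, adjusted p = 0.197 with an estimated correlation). Clock genes had 8 of 12 higher, 2 lower and 2 not called (median 0.68, camera adjusted p = 0.036, adjusted p = 0.413 with an estimated correlation). Stomatal lineage genes had 7 of 9 higher, 0 lower and 2 not called (median 0.64, camera adjusted p = 0.036, adjusted p = 0.338 with an estimated correlation). Counts of all 3 lists were the same adjusted over the list alone. The clock gene PRR9 rose from 4.5 ± 0.292 to 38.3 ± 1.17 FPKM, and the auxin repressor gene IAA6 fell from 10.9 ± 0.965 to 1.11 ± 0.108 FPKM. SPCH, which starts the stomatal lineage, rose from 1.82 ± 0.138 to 4.47 ± 0.61 FPKM. The ribosomal protein, photosynthesis, aquaporin, auxin, clock and stomatal calls were each lost or turned in direction under at least 1 of quantile normalization and removal of a transcript length trend. The stomatal median stayed at 0.60 with quantile normalization (camera adjusted p = 0.104). That call held with the length trend removed (0.0164) and with all 3 trends removed (0.0255). The auxin call was also lost without Col-0 0 min replicate 3 (camera adjusted p = 0.0576), dcp5-1 0 min replicate 2 (0.0517) or dcp5-1 0 min replicate 3 (0.0536). The 20 lists that did not pass had camera adjusted p between 0.0515 and 0.998.

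Fold change went with transcript length in this comparison. Over 18708 nuclear protein-coding genes the median log2 fold change in Col-0 was -0.43 for the 6236 genes with the shortest transcripts (median 990 nt), 0.02 for the 6236 in the middle (median 1620 nt) and 0.37 for the 6236 longest (median 2520 nt). Spearman rho was 0.509 across genes, which are not independent replicates. In dcp5-1 the medians were -0.29, 0.07 and 0.28 (rho 0.437 across genes). The ribosomal protein genes (median transcript 1069 nt), photosynthesis genes (1264 nt) and aquaporins (1397 nt), which were mostly lower, have shorter transcripts than the 1622 nt median of all genes. The decapping (2668 nt) and clock (2381 nt) genes, which were mostly higher, have longer ones. The ABA effectors, with a median of 1033 nt, moved against the trend. With the length trend removed, the median was 2.27 for the ABA effectors and 0.32 for the decapping genes (camera adjusted p = 0.00341).

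**Figure D3:**
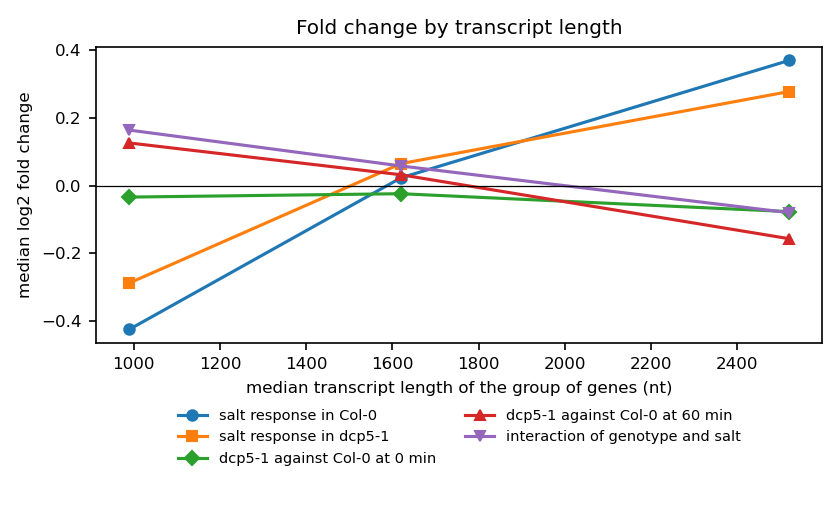
Median log2 fold change (vertical axis) of nuclear protein-coding genes against the median transcript length in nt of each of 3 groups of 6236 genes. Each line is 1 comparison. The salt comparisons run from -0.43 and -0.29 at 990 nt to 0.37 and 0.28 at 2520 nt, and the genotype difference at 60 min runs from 0.13 to -0.16.

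In dcp5-1, 60 min in NaCl raised the same ABA markers. RD26 rose from 7.25 ± 1.27 to 319 ± 9.76 FPKM (mean ± SD, n = 3; log2 fold change 5.29, SE 0.117, limma with Benjamini-Hochberg adjusted p = 1.54e-11). NAC019, a close relative of RD26, rose from 2.36 ± 0.184 to 96.3 ± 2.71 FPKM (log2 fold change 4.86, SE 0.078, limma adjusted p = 1.53e-12). PUB19 rose by 4.77 and RD29A by 4.56 log2 units. JAZ8, PHI-1, EXO, TCH4 and DDF1 fell by 5.87, fell by 5.86, fell by 5.51, fell by 5.02 and fell by 4.56 log2 units. In all, 6967 genes were higher and 6284 lower, 884 and 1302 of them by at least 1 log2 unit. ABA effectors passed as a list (17 of 18 higher, 1 lower, 0 not called, the same adjusted over the list alone; median 1.63, camera adjusted p = 6.96e-08, adjusted p = 0.0268 with an estimated correlation). So did clade A PP2C phosphatases (8 of 8 higher, also adjusted over the list alone; median 2.55, camera adjusted p = 1.15e-06, adjusted p = 0.069 with an estimated correlation). Decapping components passed too (17 of 20 higher, 1 lower, 2 not called, and 18 and 1 adjusted over the list alone; median 0.56, camera adjusted p = 0.000112, adjusted p = 0.0923 with an estimated correlation), and so did cell wall growth (3 of 14 higher, 9 lower, 2 not called, the same adjusted over the list alone; median -0.85, camera adjusted p = 0.0185, adjusted p = 0.28 with an estimated correlation). The decapping median in dcp5-1 was 0.32 with the length trend removed, with 13 of 20 higher, and 0.27 with all 3 trends removed, with 12 higher. COR15A, a cold and drought protein gene, rose from 12.2 ± 1.16 to 129 ± 5.9 FPKM and the phosphatase gene HAI1 from 5.61 ± 0.563 to 80.3 ± 3.19 FPKM. Of 14 genes of deadenylation and tandem zinc finger proteins, which shorten or bind mRNA tails, 11 were higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.06). The deadenylase gene CAF1A fell from 170 ± 6.81 to 12.8 ± 1.33 FPKM. The 26 lists that did not pass had camera adjusted p between 0.0563 and 0.963. The salt responses of the genotypes share no library. Between them 5739 genes were higher in both (2532 for independent lists) and 5401 lower in both (2242 for independent lists), with Pearson r = 0.809 and Spearman rho = 0.864 across genes. Both sets of calls use 1 spread per gene from all 12 libraries, and both responses went with transcript length. Independent lists are therefore only a rough reference.

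RBCS1A, a Rubisco small subunit gene, is listed at 0 in all 6 libraries of 0 min and at 9548 to 16311 FPKM in the 6 libraries of 60 min, while RBCS2B stands at 12800 ± 951 FPKM in Col-0 at 0 min. No fold change is given for RBCS1A, and it was left out of the photosynthesis list. Whether its zeros stem from transcript level or from the quantification was not tested.

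At 0 min, ESM1, which steers glucosinolate breakdown, had 4.95 ± 0.74 FPKM in Col-0 and 99.9 ± 3.67 FPKM in dcp5-1 (mean ± SD, n = 3; log2 fold change 4.09, SE 0.076, limma with Benjamini-Hochberg adjusted p = 1.13e-10). ELIP1, an early light-induced protein gene, had 29.7 ± 4.62 and 246 ± 12.8 FPKM (log2 fold change 3.02, SE 0.116, limma adjusted p = 1.29e-08). The chaperone gene HSP90.1 had 3.87 ± 0.462 and 34.7 ± 2.51 FPKM (log2 fold change 2.88, SE 0.075, limma adjusted p = 6.87e-10). HSP17.6A and HSP17.6II, small heat shock protein genes, were higher by 2.77 and 2.50 log2 units. OLEO2, an oleosin gene of seed oil bodies, had 16.4 ± 1.58 FPKM in Col-0 and 0.791 ± 0.0916 FPKM in dcp5-1 (log2 fold change -3.28, SE 0.137, limma adjusted p = 2.28e-08). The aldolase gene FBA5 (331 ± 64 and 41.8 ± 1.59 FPKM), and the kinase gene CIPK20 (33.9 ± 1.75 and 5.59 ± 0.435 FPKM) were lower in dcp5-1. The seed peroxiredoxin gene PER1 (8.95 ± 0.61 and 1.18 ± 0.222 FPKM) and the late embryogenesis gene EM6 (17.3 ± 3.44 and 3.06 ± 0.251 FPKM) were also lower. Of 19876 genes 3731 were higher and 5582 lower in dcp5-1, 192 and 370 of them by at least 1 log2 unit. The fit shares 1 spread per gene over all 4 groups, although replicates of Col-0 at 0 min varied most. Fitted on only the 6 libraries compared, 3032 were higher and 4549 lower, with 80.1% of the calls kept. With a transcript length trend removed, which also re-centres each library, the counts were 4732 and 4695.

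Heat shock genes were higher and photosynthesis genes and stress transcription factors lower in dcp5-1 at 0 min. Of 21 photosynthesis genes none was higher, 19 were lower and 2 not called, the same adjusted over the list alone (median -0.83, camera adjusted p = 7.38e-08, adjusted p = 0.297 with an estimated correlation). The photosynthesis median was -0.31 with quantile normalization and -0.38 with length, GC content and abundance trends removed. LHCA2 had 2470 ± 349 FPKM in Col-0 and 1180 ± 56.1 FPKM in dcp5-1. LHCB4.2, like LHCA2 a light-harvesting protein gene, had 2810 ± 398 and 1350 ± 33 FPKM. Of 19 heat shock and unfolded protein genes 14 were higher, 2 lower and 3 not called, and 14 and 4 adjusted over the list alone (median 0.57, camera adjusted p = 3.12e-06, adjusted p = 0.046 with an estimated correlation). Of 34 stress transcription factors 2 were higher, 24 lower and 8 not called, the same adjusted over the list alone (median -0.64, camera adjusted p = 7.04e-06, adjusted p = 0.046 with an estimated correlation). ERF6, an ethylene response factor of stress, had 63.7 ± 13.5 FPKM in Col-0 and 13.7 ± 0.28 FPKM in dcp5-1. CBF2, a cold response factor, had 42.4 ± 6.74 and 13.0 ± 1.5 FPKM. Lower as groups were also deadenylation and zinc finger genes (2 of 14 higher, 10 lower, 2 not called; median -0.59, camera adjusted p = 0.0026, adjusted p = 0.163 with an estimated correlation). Jasmonate genes were lower (2 of 19 higher, 12 lower, 5 not called; median -0.33, camera adjusted p = 0.006, adjusted p = 0.152 with an estimated correlation). So were genes of proline, raffinose and starch (1 of 13 higher, 8 lower, 4 not called; median -0.46, camera adjusted p = 0.00725, adjusted p = 0.152 with an estimated correlation) and ion transport genes (1 of 20 higher, 10 lower, 9 not called; median -0.25, camera adjusted p = 0.0366, adjusted p = 0.152 with an estimated correlation). Counts of these 4 lists were the same adjusted over the list alone. With all 3 trends removed the median was -0.20 for jasmonate genes and -0.30 for genes of proline, raffinose and starch. Nearer the threshold were ethylene genes (2 of 14 higher, 7 lower, 5 not called, the same adjusted over the list alone; median -0.28, camera adjusted p = 0.0454, adjusted p = 0.266 with an estimated correlation). ABA synthesis and breakdown was near it too (0 of 8 higher, 6 lower, 2 not called, and 1 and 6 adjusted over the list alone; median -0.36, camera adjusted p = 0.0495, adjusted p = 0.163 with an estimated correlation), as were clade A PP2C phosphatases (0 of 8 higher, 5 lower, 3 not called, the same adjusted over the list alone; median -0.22, camera adjusted p = 0.0495, adjusted p = 0.297 with an estimated correlation). The zinc finger gene OZF1 had 19.2 ± 2.5 and 6.46 ± 0.713 FPKM in Col-0 and dcp5-1. The lipoxygenase gene LOX2 of jasmonate synthesis had 13.1 ± 0.271 and 5.75 ± 0.0743 FPKM, and the sugar-starvation gene DIN10 had 159 ± 1.8 and 60.3 ± 3.02 FPKM. The vacuolar proton pump gene AVP1 had 52.2 ± 7.03 and 31.5 ± 0.645 FPKM, and the phosphatase gene PP2CA had 49.9 ± 1.99 and 26.6 ± 0.804 FPKM in Col-0 and dcp5-1. The ion transport call was lost without Col-0 0 min replicate 1 (camera adjusted p = 0.056). The ethylene call was lost without Col-0 0 min replicate 2 or 3 (0.0503 and 0.0576), and the ABA synthesis call was lost without replicate 1 or 3 of any group (0.0504 to 0.061). The PP2C call was lost without replicate 1 or 3 of Col-0 at either time, dcp5-1 0 min replicate 3 or any dcp5-1 60 min replicate (0.0504 to 0.0891), and with the length trend (0.0588) or all 3 trends (0.0639) removed. With a block for replicate number the ethylene, ABA synthesis and PP2C calls were all lost (camera adjusted p = 0.0514 for each). The 20 lists left, decapping components among them (3 of 20 higher, 9 lower with DCP5 itself, 8 not called, and 3 and 10 adjusted over the list alone; camera adjusted p = 0.112), did not pass.

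**Figure D4:**
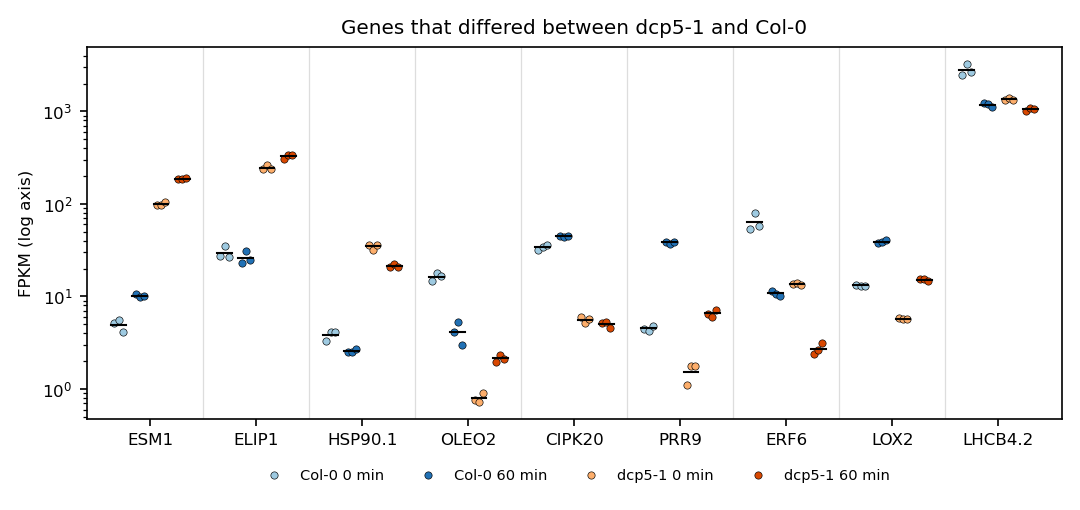
FPKM (log axis) of 9 genes in Col-0 and dcp5-1 at 0 and 60 min; points are libraries and short lines are means of 3 libraries. ESM1, ELIP1 and HSP90.1 lie higher in dcp5-1 at both times. OLEO2, CIPK20, PRR9, ERF6, LOX2 and LHCB4.2 lie lower.

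After 60 min in NaCl, dcp5-1 again had more ESM1, with 188 ± 0.627 FPKM against 10.2 ± 0.382 FPKM in Col-0 (mean ± SD, n = 3; log2 fold change 4.08, SE 0.076, limma with Benjamini-Hochberg adjusted p = 1.16e-10). ELIP1 (26.3 ± 4.39 and 326 ± 15.8 FPKM), HSP17.6II (9.83 ± 1.57 and 87.8 ± 4.88 FPKM), the plastid envelope protein gene OEP6 (80.5 ± 5.84 and 579 ± 11.9 FPKM) and HSP90.1 (2.57 ± 0.0959 and 21.4 ± 0.669 FPKM) were also higher in dcp5-1 than in Col-0. CIPK20 had 44.6 ± 0.238 FPKM in Col-0 and 5.04 ± 0.393 FPKM in dcp5-1 (log2 fold change -2.92, SE 0.064, limma adjusted p = 2.61e-10). The clock gene PRR9 had 38.3 ± 1.17 and 6.56 ± 0.623 FPKM (log2 fold change -2.38, SE 0.104, limma adjusted p = 2.53e-08). The cutinase gene CDEF1 (45.1 ± 0.748 and 5.65 ± 0.325 FPKM) and FBA5 (102 ± 5.36 and 16.5 ± 0.306 FPKM) were lower as well. The locus MIR852 is listed at 0 in all 6 dcp5-1 libraries and at a mean of 7.92 FPKM in Col-0 at 60 min. In all, 5394 genes were higher and 5437 lower, 239 and 243 of them by at least 1 log2 unit. With median-of-ratios rescaling 4732 were higher and 6170 lower. The genotype differences at 0 and 60 min share no library. Of all genes, 2651 were higher at both times (1013 for independent lists) and 3242 lower at both (1527 for independent lists), with r = 0.481 and rho = 0.604 across genes. These calls, too, use 1 spread per gene from all 12 libraries.

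Ribosomal protein genes joined the heat shock genes on the higher side at 60 min. All 15 ribosomal protein genes were higher in dcp5-1, also adjusted over the list alone (median 0.51, camera adjusted p = 1.13e-05, adjusted p = 0.398 with an estimated correlation). With all 3 trends removed their median was 0.30, with 12 of 15 higher. RPS5B had 54.3 ± 0.576 FPKM in Col-0 and 97.5 ± 1.73 FPKM in dcp5-1. Ribosome biogenesis genes had 7 of 10 higher, 1 lower and 2 not called, the same adjusted over the list alone (median 0.34, camera adjusted p = 0.0252, adjusted p = 0.199 with an estimated correlation). The nucleolar protein gene NOP56 had 23.2 ± 1.09 and 37.7 ± 1.46 FPKM. Of 19 heat shock genes 12 were higher, 3 lower and 4 not called, the same adjusted over the list alone (median 0.66, camera adjusted p = 0.000166, adjusted p = 0.0872 with an estimated correlation). Of 19 jasmonate genes 1 was higher, 15 were lower and 3 not called, and 2 and 15 adjusted over the list alone (median -0.62, camera adjusted p = 1.13e-05, adjusted p = 0.0872 with an estimated correlation). The higher member was AOC3, an allene oxide cyclase gene (8.62 ± 0.669 and 21.4 ± 0.857 FPKM). The lower ones included LOX2 (39.0 ± 1.27 and 15.1 ± 0.315 FPKM) and MYC2, the main jasmonate transcription factor gene (49.2 ± 1.55 and 20.5 ± 0.749 FPKM). Stress transcription factors had 2 of 34 higher, 23 lower and 9 not called, and 3 and 24 adjusted over the list alone (median -0.36, camera adjusted p = 0.000166, adjusted p = 0.0872 with an estimated correlation). WRKY33, a factor of defence, had 57.2 ± 1.63 and 19.5 ± 0.392 FPKM in Col-0 and dcp5-1, and NAC019 had 56.6 ± 1.14 and 96.3 ± 2.71 FPKM. Decapping components had 2 of 20 higher, 13 lower with DCP5 itself and 5 not called, and 2 and 15 adjusted over the list alone (median -0.30, camera adjusted p = 0.00277, adjusted p = 0.158 with an estimated correlation). The camera test of this list included DCP5, the mutated gene, and was not run without it. The call for decapping components was lost with the length trend removed (camera adjusted p = 0.144). The median log2 fold change of all genes ran from 0.13 for the shortest transcripts to -0.16 for the longest at 60 min. Genes of proline, raffinose and starch passed (1 of 13 higher, 8 lower, 4 not called, the same adjusted over the list alone; median -0.30, camera adjusted p = 0.00585, adjusted p = 0.158 with an estimated correlation). Stomatal lineage genes passed too (0 of 9 higher, 8 lower, 1 not called, the same adjusted over the list alone; median -0.39, camera adjusted p = 0.0138, adjusted p = 0.212 with an estimated correlation), as did ABA effectors (2 of 18 higher, 11 lower, 5 not called, and 3 and 11 adjusted over the list alone; median -0.27, camera adjusted p = 0.0477, adjusted p = 0.228 with an estimated correlation). The median for proline, raffinose and starch was -0.13 with the length trend removed and -0.15 with all 3 trends removed. The stomatal patterning receptor gene TMM had 9.45 ± 0.876 and 4.35 ± 0.184 FPKM, and RD29B, an ABA-induced gene beside RD29A, had 51.1 ± 3.51 and 27.7 ± 0.48 FPKM. The ABA effector call was lost without Col-0 0 min replicate 1 or 2, Col-0 60 min replicate 2, dcp5-1 0 min replicate 2 or dcp5-1 60 min replicate 1 or 3 (camera adjusted p = 0.0528 to 0.0672).

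**Figure D5:**
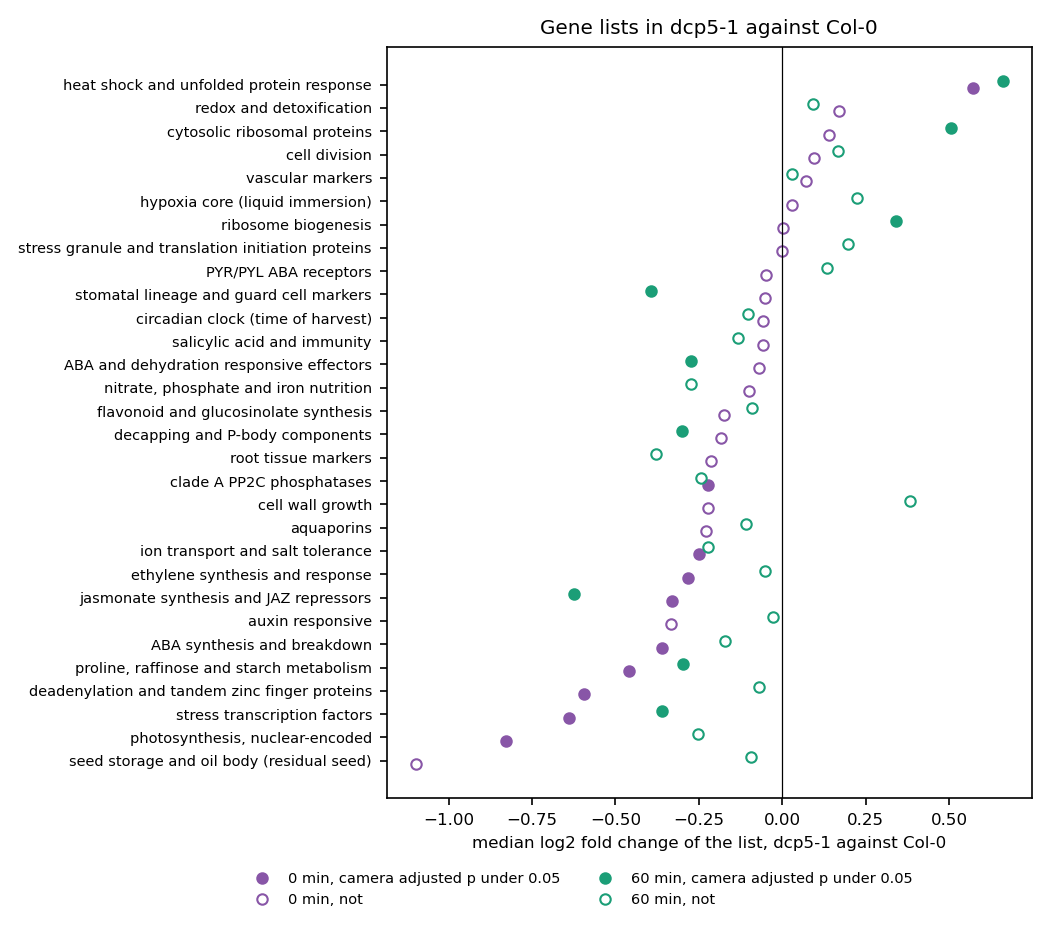
Median log2 fold change, dcp5-1 against Col-0 (horizontal axis), of each of 30 gene lists (vertical axis) at 0 and 60 min; filled points have a camera adjusted p below 0.05. Heat shock genes lie at 0.57 and 0.66, photosynthesis genes at -0.83 and -0.25, and ribosomal protein genes at 0.14 and 0.51.

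The salt response itself differed between the genotypes for 4850 genes. Of these, 3248 had the higher signed log2 fold change in dcp5-1 and 1602 the lower. With quantile normalization, which centres the libraries alike, the numbers were 2033 and 2077. As deposited, 2055 of the 3248 were lower at 60 min in the mean salt response, so their fall was weaker or reversed in dcp5-1. Another 850 were higher. Of the 1602, 1025 were higher in the mean salt response and 333 lower. The remaining 587 genes were not called in it. OLEO2 went from 16.4 ± 1.58 to 4.12 ± 1.12 FPKM in Col-0 and from 0.791 ± 0.0916 to 2.14 ± 0.206 FPKM in dcp5-1 (mean ± SD, n = 3; interaction log2 fold change 2.59, SE 0.194, limma with Benjamini-Hochberg adjusted p = 2.35e-05). EARLI1, which encodes a lipid transfer-like protein, went from 63.7 ± 7.63 to 111 ± 7.88 FPKM in Col-0 and from 15.9 ± 0.449 to 112 ± 3.83 FPKM in dcp5-1 (interaction 1.95, SE 0.113, limma adjusted p = 9.31e-06). Its neighbour AZI1, a systemic immunity gene, had an interaction of 1.84. HEC1, a bHLH factor gene, rose from 2.49 ± 0.416 to 6.4 ± 0.801 FPKM in Col-0 and from 2.34 ± 0.162 to 24.0 ± 1.34 FPKM in dcp5-1. The precursor locus MIR167d had an interaction of 2.12 from Col-0 values at 0 min of 13.4 ± 6.1 FPKM. On the other side were PROPEP3, the precursor gene of an immune peptide (interaction -1.76; 9.44 ± 3.23 to 6.65 ± 0.791 FPKM in Col-0 and 18.7 ± 2.26 to 3.37 ± 0.504 FPKM in dcp5-1). Lower interactions were also found for the locus MIR863 (-1.56, SE 0.478), bHLH071 (-1.41), the cambium factor gene WOX4 (-1.31) and PRE1 (-1.31). The MIR863 call was lost on leaving out any 1 library other than Col-0 0 min replicate 1, Col-0 60 min replicate 3 or dcp5-1 0 min replicate 1 (limma adjusted p = 0.0523 to 0.0819). It was lost as well with no filter (interaction -1.56, limma adjusted p = 0.0647), with the length trend removed (-1.27, 0.201) and with all 3 trends removed (-1.17, 0.24). By at least 1 log2 unit, 121 genes had the higher and 52 the lower signed log2 fold change in dcp5-1. Of all genes, 263 were called in opposite directions in the genotypes with the interaction called, 188 of them lower in Col-0 and higher in dcp5-1.

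As deposited, photosynthesis and ribosomal protein genes had mostly positive interactions. Of 21 photosynthesis genes 16 had a called positive interaction, 0 a negative one and 5 none, the same adjusted over the list alone (median 0.57, camera adjusted p = 5.04e-08, adjusted p = 0.399 with an estimated correlation). LHCB4.2 went from 2810 ± 398 to 1180 ± 56.1 FPKM in Col-0 and from 1350 ± 33 to 1050 ± 33.3 FPKM in dcp5-1. Of 15 ribosomal protein genes 11 were positive, 0 negative and 4 not called, and 13 and 0 adjusted over the list alone (median 0.43, camera adjusted p = 4.82e-05, adjusted p = 0.399 with an estimated correlation). RPL10A went from 1200 ± 209 to 528 ± 23.8 FPKM in Col-0 and from 895 ± 25.4 to 640 ± 14.6 FPKM in dcp5-1. Cell wall growth genes were also positive (9 of 14 positive, 0 negative, 5 not called, and 10 and 1 adjusted over the list alone; median 0.37, camera adjusted p = 0.000137, adjusted p = 0.164 with an estimated correlation). So were ethylene genes (9 of 14 positive, 1 negative, 4 not called, the same adjusted over the list alone; median 0.50, camera adjusted p = 0.00224, adjusted p = 0.164 with an estimated correlation). EXPA8, an expansin gene, went from 25.7 ± 3.98 to 14.5 ± 1.44 FPKM in Col-0 and from 21.1 ± 1.39 to 28.0 ± 1.36 FPKM in dcp5-1. Jasmonate genes were negative (2 of 19 positive, 11 negative, 6 not called, and 3 and 11 adjusted over the list alone; median -0.24, camera adjusted p = 0.00044, adjusted p = 0.164 with an estimated correlation). So were stomatal lineage genes (0 of 9 positive, 3 negative, 6 not called, the same adjusted over the list alone; median -0.36, camera adjusted p = 0.00223, adjusted p = 0.164 with an estimated correlation). LOX3, a wound-induced lipoxygenase gene, fell from 21.3 ± 0.365 to 13.3 ± 0.599 FPKM in Col-0 and from 16.8 ± 0.432 to 6.06 ± 0.31 FPKM in dcp5-1. Seed storage and oil body genes passed as well (4 of 6 positive, 0 negative, 2 not called, the same adjusted over the list alone; median 1.29, camera adjusted p = 0.00836, adjusted p = 0.164 with an estimated correlation). These 6 had a median of 1.94 FPKM, against 11.1 for all genes, and most members of that list lay below the filter of 1 FPKM. Ribosome biogenesis passed (5 of 10 positive, 0 negative, 5 not called, the same adjusted over the list alone; median 0.25, camera adjusted p = 0.0195, adjusted p = 0.207 with an estimated correlation), and so did aquaporins (4 of 19 positive, 0 negative, 15 not called, the same adjusted over the list alone; median 0.28, camera adjusted p = 0.0343, adjusted p = 0.659 with an estimated correlation). The jasmonate median was -0.49 with quantile normalization and -0.39 with all 3 trends removed, and the cell wall median was 0.21 with quantile normalization. The photosynthesis median was 0.33 with quantile normalization, with 8 of 21 genes called, and 0.15 with length, GC content and abundance trends removed (camera adjusted p = 0.00433). The ribosomal protein call was lost with quantile normalization (camera adjusted p = 0.052). The aquaporin call was lost with quantile normalization too (median 0.03, camera adjusted p = 0.949). Its median changed sign, and the ribosomal protein call was lost too, when trends with length, GC content and abundance were removed. The aquaporin call was also lost without Col-0 0 min replicate 2 (camera adjusted p = 0.201), Col-0 60 min replicate 3 (0.0721), dcp5-1 0 min replicate 3 (0.0572) or dcp5-1 60 min replicate 2 or 3 (0.0531 and 0.0559). The interaction itself went with abundance and length. Its median was 0.21 for the 6236 most abundant genes and -0.08 for the 6236 least abundant, and 0.16 for the shortest and -0.08 for the longest transcripts.

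Whether dcp5-1 responded less was measured over the 15416 genes called in the mean salt response of both genotypes. The median interaction signed by the direction of that response was -0.11 log2 units (exact test over 400 regroupings of the genotypes within each time, two-sided p = 0.065, 0.0975 after Benjamini-Hochberg adjustment over 3 tests; the smallest p this design can give is 0.005). It was -0.05 for the 7948 genes higher at 60 min (exact p = 0.445, adjusted 0.445) and -0.18 for the 7468 genes lower at 60 min (exact p = 0.01, adjusted 0.03). With median-of-ratios rescaling the medians of the higher and lower genes were both -0.116 (exact p = 0.09 and 0.01), and with quantile normalization they were -0.082 and -0.101 (exact p = 0.085 and 0.065). The gap between higher and lower genes thus depended on the scaling. Over all genes the median was -0.062 with the length trend removed (exact p = 0.03), -0.062 with all 3 trends removed (exact p = 0.025), and -0.205 among genes with a mean response of at least 1 log2 unit. As deposited, leaving out any 1 library gave -0.22 to -0.15 for the lower genes. Of the 15416 genes 9979 had the smaller and 5437 the larger response in dcp5-1. All these exact p-values assume no genotype effect at either time. Yet 9313 genes differed by genotype at 0 min and 10831 at 60 min, so the p-values do not isolate a difference in the response.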

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

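In this part, the tests with rescaling, with length, GC content and abundance together, and of ungerminated seed were chosen only after the results were seen, while what the other tests would show was written down before their results; settings that remove a length trend were added once the data had been examined.

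The salt response differed between the genotypes for 4850 genes, 3248 of them with a positive interaction. For 2055 of the 3248 this meant a weaker or reversed fall in dcp5-1. In 3 of 100 drawn regroupings of the libraries, the real one included, as many genes were called, a share below 0.05. The other 2 called 5428 and 12131. Next came 3 that called 3834 to 4207, and the real count fell to 3510 on leaving out 1 library. The highest, 12131, came from a regrouping that swaps the genotypes at 1 time and so measures the mean genotype difference. Regroupings thus also carry the genotype difference itself, called for 9313 genes at 0 min and 10831 at 60 min. This test therefore does not exclude chance for the interaction. Of the calls 67.0% were higher as deposited, 51.5% with median-of-ratios rescaling and 59.1% with a length trend removed (58.6% to 61.5% leaving out 1 library). The 59.1% lay in the range set beforehand for a length trend, and the 51.5% in that set afterwards for scaling. Both settings also re-centre each library, which can itself move this share. Meeting these ranges therefore decides neither for nor against scaling or transcript length. Without replicate 2 of Col-0 at 0 min, which stands apart on the third principal component, 67.1% were higher, which argues against that library as the source. A genotype effect on the response stays open beside chance, scaling and length.

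Within that pattern, the photosynthesis list (median interaction 0.568) and the ribosomal protein list (0.425) were tested on their own. Both passed camera at the preset correlation but not with an estimated correlation. With the length trend removed the medians were 0.533 (camera adjusted p = 5.08e-10) and 0.27 (9.86e-05), and without replicate 2 of Col-0 at 0 min 0.491 and 0.355, so neither a length trend nor that library explains them alone. With length, GC content and abundance trends removed they were 0.15 (camera adjusted p = 0.00433) and 0.027 (0.386), and since these genes are abundant (median 2200 and 365 FPKM, against 11.1 for all), a trend with abundance and a change of these genes cannot be told apart.

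As deposited, genes lower at 60 min than at 0 min had a median signed interaction of -0.182 (exact p = 0.01), against -0.052 for the higher genes. With median-of-ratios rescaling both were -0.116, so a smaller response particular to the lower genes is not shown. By at least 1 log2 unit, 1149 genes were lower in both genotypes. Listed touch and wound genes had a median log2 fold change of -1.444 in Col-0 and -1.52 in dcp5-1, with 10 of 14 lower in both, which is consistent with the decay of a response to handling before 0 min. With the length trend removed 64.1% of the 1149 genes (736) stayed lower by that much, so a length trend may explain part of them, and the test left this undecided. An effect of NaCl itself stays open, as the series holds no 60 min sample without NaCl.

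OLEO2 had an interaction of 2.588, the highest of all named genes, and the seed storage and oil body list a median of 1.293 over the 6 members tested. That list passed camera at the preset correlation but not with an estimated correlation. Ungerminated seed in the Col-0 libraries at 0 min would raise the abundant storage protein transcripts as well, but the summed FPKM of 8 storage protein genes was alike in Col-0 and dcp5-1 at 0 min (ratio 1.02; 5.23, 5.21 and 5.83 against 6.03, 5.84 and 4.13), while OLEO2 differed 20.7-fold, which argues against that explanation. At 60 min the sums were 1.81, 2.53 and 2.55 in Col-0 and 6.3, 4.79 and 7.41 in dcp5-1. The genotypes thus differed in the change of these sums over time in the same direction as for OLEO2, which was not tested. All these sums are low for 8 genes, with a mean per gene below the filter of 1 FPKM, which limits both comparisons. What raises these genes in one genotype stays open.

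Other genes and lists were called in the interaction, genes with limma and lists with camera at the preset correlation. In opposite directions 263 genes were called. MIR167d had an interaction of 2.115, EARLI1 1.949, AZI1 1.837 and HEC1 1.816, and PROPEP3 had -1.758, MIR863 -1.555, bHLH071 -1.411, WOX4 -1.314 and PRE1 -1.311. The MIR863 call was lost with no filter (limma adjusted p = 0.0647), with the length trend removed (0.201) and on leaving out most single libraries. List medians were -0.244 for jasmonate, 0.504 for ethylene, 0.365 for cell wall growth, 0.283 for aquaporins, 0.253 for ribosome biogenesis and -0.358 for stomatal lineage genes. None of these lists passed with an estimated correlation (camera adjusted p = 0.164 to 0.659). The aquaporin call was also lost with quantile normalization (median 0.034, camera adjusted p = 0.949). Its median was -0.003 with length, GC content and abundance trends removed (camera adjusted p = 0.478).

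For the 4 comparisons of 3 against 3 libraries, 10 splits are too few to give a share below 0.05. The real split called 14315 genes in Col-0, where the highest other split called 1, and in dcp5-1 it called 13251, where the highest other called 1. For the genotypes the real splits called 9313 at 0 min and 10831 at 60 min, where the highest others called 2 and 2. For the mean salt response 1 of 100 drawn regroupings, the real one, called as many as 15416 genes (highest other 9010). This share is below 0.05, so chance in the grouping of these libraries is an unlikely source of the count. The replicates may be technical, so chance differences between cultures are not covered.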

How the results depend on the processing

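In this part, the tests with rescaling, quantile normalization, removed trends, a mean of at least 5 FPKM, no variance trend, protein-coding genes only and exact zeros left out were chosen only after the results were seen.

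With a further threshold of 1 log2 unit, fewer genes pass by construction: 3175 for salt in Col-0, 2186 in dcp5-1, 562 and 482 for the genotypes at 0 and 60 min, 173 for the interaction and 2541 for the mean salt response. In the other alternatives each of these 6 counts stayed within 1.5 times its value, but the genes called changed more. Of the 4850 interaction calls, 82.7% were kept with median-of-ratios rescaling and 68.2% with quantile normalization. With the length trend removed 68.9% were kept, and with length, GC content and abundance trends removed 53%. For salt in Col-0 the last setting kept 70.6% of the 14315 calls and called 805 genes in the opposite direction. With a block for replicate number the counts were 14253, 13106, 9165, 10695, 4560 and 15345. Replicate numbers do not pair the samples: over 18 pairs of same-numbered libraries the deviations from the group means correlated at -0.132 to 0.255, with 2 pairs over 0.1, and 5 of 12 libraries went best with their own number. Leaving out 1 library gave 3510 to 5761 interaction calls.

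The share of calls that were higher did change, both in settings that re-centre each library and in others. For the interaction 67.0% were higher as deposited, 51.5% with median-of-ratios rescaling, 49.5% with quantile normalization, 59.1% with the length trend removed and 50.2% with length, GC content and abundance trends removed. For dcp5-1 against Col-0 at 0 min 40.1% were higher as deposited, and 51.6%, 50.2% and 51.3% with quantile normalization, the length trend removed and all 3 trends removed. With the length trend removed, 613 genes for salt in Col-0 and 186 in dcp5-1 were called in the opposite direction. For dcp5-1 against Col-0 at 60 min 49.8% were higher as deposited and 43.4% with median-of-ratios rescaling. Without re-centring, the share for salt in Col-0 went from 50.5% to 32.9% at 1 log2 unit, and that of the interaction from 67.0% to 72.9% at a mean of at least 5 FPKM.

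The size of the response in dcp5-1 was -0.107; among genes with a mean response of at least 1 log2 unit it was -0.205, and it was -0.062 with the length trend removed and -0.062 with all 3 trends removed. The cause was not tested.

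Of the 150 list tests 42 passed; camera with an estimated correlation passed 4, the directional fry test 113 and the mixed fry test 149. These differ by construction, since fry does not compare a list with other genes. Lists that passed were also refitted with a replicate block, without each library, with rescaling, with quantile normalization and with trends removed. In these settings a list that passed lost its call 57 times, 4 of them with a median of the opposite sign. The 57 leave out the estimated correlation and the fry tests. For salt in Col-0 the aquaporin median turned to 0.066 with quantile normalization and the ribosomal protein median to 0.223 with quantile normalization and 0.097 with all 3 trends removed; the aquaporin interaction turned to -0.003 with all 3 trends removed. The cause was not tested. The block for replicate number took 3 calls at 0 min just past the threshold (ABA synthesis, PP2C and ethylene lists, camera adjusted p = 0.0514 for each).

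Of 95 named gene results under 19 alternatives, 2 changed direction and 3 (RAB18, LSM1A and MIR863) lost the call. RAB18 for salt in Col-0 turned to 0.215 with all 3 trends removed, and LSM1A turned to 0.045 with the length trend removed and 0.014 with all 3. The DCP5 interaction, not called as deposited, was -0.438 with quantile normalization (limma adjusted p = 0.00045). DCP5 was called lower in dcp5-1 under all 19, with log2 fold changes of -1.952 to -1.658 at 0 min and -2.134 to -1.806 at 60 min.

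The count-based tests, size factors and count filters planned at first were not run, because the values are not counts. In simulated data 82.1% of genes changed by 0.5 log2 units were recovered, so smaller changes can be missed.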

Other observations

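No tests in this part were chosen only after the result was seen.

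For salt in Col-0 the lists that did not pass had these counts higher, lower and not called, which were the same adjusted over the list alone unless given. ABA synthesis and breakdown had 5, 3 and 0 (camera adjusted p = 0.265), ABA receptors 2, 7 and 0 (0.0662, median -1.77), ion transport 11, 2 and 7 (0.0515), and proline with raffinose and starch 8, 4 and 1 (0.198). Deadenylation had 9, 3 and 2 (0.231), stress granule proteins 3, 12 and 2 (0.311), jasmonate 9, 10 and 0 (0.848), ethylene 9, 4 and 1 (0.305) and ribosome biogenesis 5, 2 and 3 (0.514). Heat shock genes had 6, 7 and 6 (0.914), with a median of -0.02 and a mean of 0.19.

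Redox genes had 6, 8 and 2 (camera adjusted p = 0.998), and 7 and 8 adjusted over the list alone, with a median of -0.18 and a mean of 0.07. Salicylic acid genes had 2, 4 and 2 (0.596), flavonoid and glucosinolate genes 9, 7 and 1 (0.514), nutrition genes 3, 6 and 1 (0.721) and seed storage genes 1, 4 and 1 (0.231). Hypoxia genes, a sign of liquid immersion, had 3, 0 and 4 (0.378). Root markers had 4, 4 and 4 (0.914), with a median of 0.11 and a mean of -0.03. Vascular markers had 2, 2 and 4 (0.721), and 1 and 1 adjusted over the list alone, and cell division genes 1, 2 and 4 (0.605), and 0 and 2 adjusted over the list alone.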
